A study of Caenorhabditis elegans with 2 samples.

How the data were processed

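Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans larvae at the L2 stage, from a strain (OP228) that carries an integrated transgene with an eGFP-tagged copy of the nuclear hormone receptor gene nhr-237 in an unc-119 mutant background. The labels put both libraries in 1 group, as biological replicates 1 and 2 of larvae of mixed sex, with a size range of 150 to 350 bp. There is therefore no contrast between groups. The comparisons made were between the 2 replicates, and between the peaks and the genome around them.

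The deposited files were region lists in the narrowPeak layout, each in the ce10 and the ce11 build. Per the file descriptions deposited with the samples, the authors called regions on each library against a control alignment at a relaxed threshold that lets background through, and called regions again on both libraries together. They then kept the regions of the pooled list that passed a threshold on the irreproducible discovery rate (IDR), which compares the ranks of regions between replicates. The peak caller, its version, the IDR threshold and the aligner are not given in the sources used here, nor is the strain or kind of sample of the control. The signal value of each region (column 7) was the authors' enrichment over the control as deposited, on a scale that belongs to its own list. The −log10 q-value (column 9) was likewise deposited by the authors, and 323 of the 350 IDR peaks shared its highest value, so peaks were ranked by signal.

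In ce11 each replicate list held 30000 regions, the pooled list held 6542 and the IDR list held 350. In ce10 the lists held 29929 regions for replicate 1, 30000 for replicate 2, 6868 for the pool and 370 for IDR. The IDR peaks were the 350 pooled regions with the highest signal, which was tested on the lists, so that a peak entered by its pooled signal and not by its presence in both replicate lists. In 328 IDR peaks the interval was 376 bp wide, so widths carried little information and the summit was used. Read counts were not analysed here, the depth of each library is unknown, and the immunoprecipitate of an untagged strain was not analysed here. Intervals given below cover counting error in peaks or genes only.

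Coordinates are in ce11, which is the WBcel235 assembly, and all region ends lay within its chromosome lengths. Gene models came from Ensembl release 115. The start of a gene is the 5′ end of its model, which in this organism is often the site of trans-splicing and not of transcription. A gene was near a peak when its start lay within 1000 bp of the summit. The ce10 lists were used only for list sizes and overlap. Calculations were done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots in matplotlib 3.10.9.

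The overlap of replicates was the percent of the 350 regions of replicate 1 with the highest signal whose summit lay within 150 bp of a summit among the 350 highest of replicate 2. It was tested one-sided against 10000 shuffles of the regions within their chromosomes. The share of peaks near protein-coding starts, and near noncoding genes (within 250 bp), was tested two-sided against shuffles of the same kind. Lists of genes were tested with the two-sided Fisher's exact test against all 19973 protein-coding genes of the 6 nuclear chromosomes. Peaks per chromosome were tested with the exact binomial test against the chromosome's share of those genes. Sequence motifs were sought within 100 bp of the summits of peaks near a start, and compared by Fisher's exact test with windows at the same offset from 10 random gene starts per peak. Signal values were compared by a permutation test of medians with 100000 resamples. Counts of peaks within 20000 bp of nhr-237 and unc-119 were tested one-sided against shuffles. Benjamini-Hochberg adjustment was applied within each family, over the 29 lists, 5 noncoding classes, 6 chromosomes and 11 motifs. Lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined, except where said and except for the tests under Other observations. That rule took the gene with the closest start within 1000 bp of each of the 25 highest peaks, up to 4 members per list past the threshold with the highest peaks, nhr-237 and unc-119. Other genes are said where they appear to have been chosen after their values were seen.

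The procedures were tested on simulated data. For the share near starts and the overlap, 350 peaks were placed at random on the real chromosomes. For the other tests, genes, chromosomes or sequence windows beside gene starts were drawn directly. Those runs check the calculation only, since genes that share a peak were not simulated. With no effect planted, 4 of 100 simulations passed the threshold for the share near starts, 2 of 100 for the overlap, 1 of 100 for any gene list, 3 of 100 for any chromosome and 0 of 20 for motifs. With 35 peaks moved onto gene starts, 79% of simulations passed, and with 35 shared regions all 100 overlap tests passed. Adding 12 ribosomal protein genes was recovered in 100% of simulations, a 1.6-fold weight on X in 77%, and a GA repeat written into 35 windows in 20 of 20.

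Alternatives were the 175 peaks with the highest signal, the 350 highest regions of either replicate alone, other distances, merging of summits within 500 bp, the closest start only, a background of the 5761 genes with a start near regions of both replicates, chromosome length in place of gene share, offset-keeping shuffles, and dinucleotide-shuffled sequences. Descriptive text files among the deposited material were read for provenance and hold no measurements.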

Results

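Binding of eGFP-tagged NHR-237, one of the large family of nuclear hormone receptors of C. elegans, was mapped by ChIP-seq in whole L2 larvae in 2 biological replicates. The 350 IDR peaks had a median signal of 58.4, with quartiles of 48.2 and 80.8 and a range from 41.9 to 507. Each library's relaxed list held 30000 regions. Signals of regions matched to the same peak were higher in replicate 1 by a median ratio of 1.93, but the scale is that of each list and the depth is unknown. With 2 libraries and 1 value per region in each list, single peaks are given without an SD.

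The first question was how far the replicates located the same regions. The 25 strongest IDR peaks all ranked within the first 26 regions of replicate 1 and the first 33 of replicate 2. IDR peaks were chosen by a signal pooled from the same 2 libraries, so their high ranks in both are partly built in. Of the 350 highest regions of replicate 1, 50.9% had a summit within 150 bp of one of the 350 highest of replicate 2, against 0.106% after shuffling (one-sided permutation p = 0.0001, the smallest possible). The shuffles allowed any position on the chromosome, so the overlap that open chromatin alone would give was not tested. Among the IDR peaks, 293 (83.7%) lay among the 350 highest regions of replicate 1 and 214 (61.1%) among those of replicate 2, with 179 in both. Across the 342 peaks with a region in both lists, which are not independent replicates, Spearman's rho of the signals was 0.451, and 0.312 without the 25 strongest. A cut on the pooled signal can lower such a correlation, since a peak weak in one replicate must be strong in the other to enter. Neither value therefore measures the agreement of the replicates over all regions. The overlap fell to 29.5% for the 1000 highest regions of each list and was 88% for the 25 highest.

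**Figure D1:**
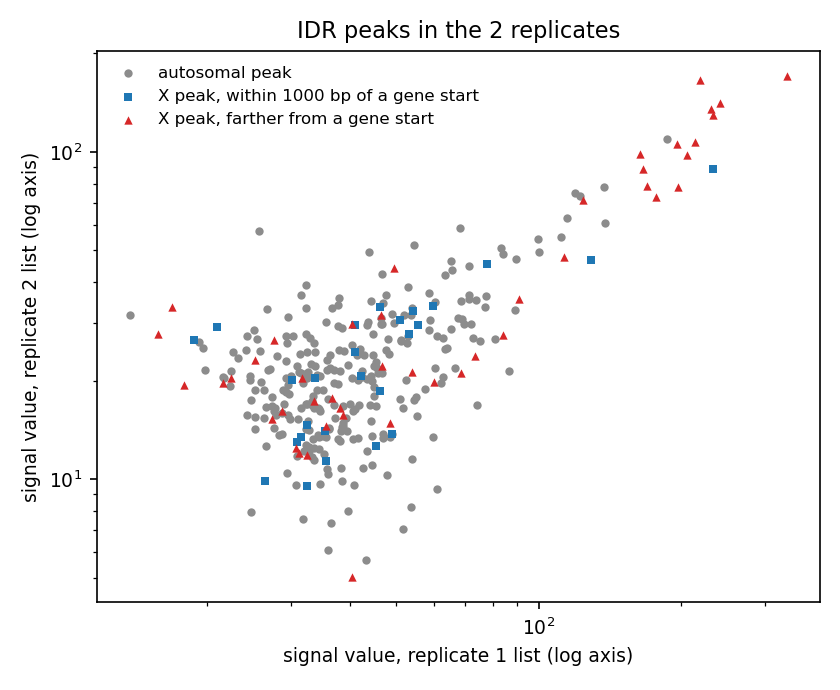
Signal value of each IDR peak in the replicate 1 list (x, log axis) and the replicate 2 list (y, log axis), for the 342 peaks with a region in both. Points are single peaks, and the X-linked peaks farther than 1000 bp from a gene start (red triangles) make up most of the upper right corner.

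The peaks lay mostly just upstream of protein-coding genes. Of the 350, 233 (66.6%, exact binomial 95% interval 61.4 to 71.5) had a summit within 1000 bp of a start, against 33.8% ± 2.50 (SD of 10000 shuffles; two-sided permutation p = 0.0002, the smallest possible). In 205 of these 233 the summit was upstream of the closest start. Over all 233 the median position was −178 bp (quartiles −306 and −86). In 96 of them (41.2%) starts on both strands lay within reach. By annotation, 267 summits of the 350 were intergenic, 53 in introns, 18 in 5′ UTRs, 6 in coding exons, 5 in 3′ UTRs and 1 in another exon. In all, 343 protein-coding genes (1.72%) had a start near a peak.

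**Figure D2:**
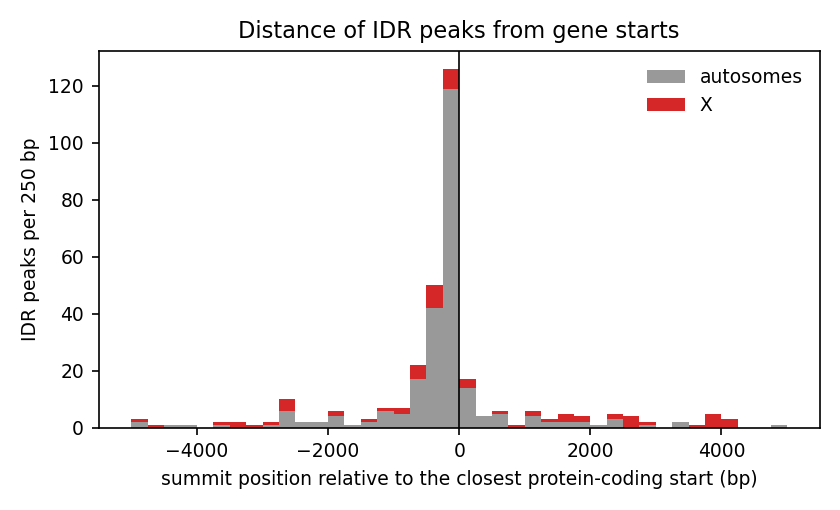
Number of IDR peaks per 250 bp (y) by position of the summit relative to the closest protein-coding start (x, bp, negative upstream), stacked for autosomes (grey) and X (red). The 250 bp just upstream hold 126 peaks, and 31 peaks farther than 5000 bp from a start are not drawn.

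The X chromosome differed from the autosomes. Only 27 of its 74 peaks (36.5%) were near a start, compared with 206 of 276 autosomal peaks (74.6%; Fisher's exact p = 2.11e-09). For X alone the share was not past the threshold against shuffling (28.9%; permutation p = 0.19), whereas on autosomes it was (35.2%; permutation p = 0.0002, the smallest possible). X also held the strongest peaks: 14 of the first 15 and 17 of the first 25 (Fisher's exact p = 1.78e-07 against the remaining peaks). Over all peaks, the median signal was 63.9 on X and 57.5 on autosomes, a difference not past the threshold (permutation p = 0.0831). These splits by chromosome were made after the data were seen.

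Of the 25 strongest peaks, 15 were on X and away from starts. The highest, at X 11094026 to 11094367 with a signal of 507, was intergenic, 3960 bp from the start of W02H3.3, and ranked first in both replicates. The peak at X 6296411 to 6296724 (signal 369) lay in an intron, with cest-16 as the closest start at 3384 bp. At X 8036304 to 8036575 (signal 294) an intergenic peak had xol-1 as the closest protein-coding start, at 4869 bp, and a tRNA gene within 250 bp of its summit. The peak at X 5429442 to 5429598 (signal 196) was in a coding exon, 15171 bp from the closest start. These genes fall outside the naming rule and were chosen after their values were seen, as landmarks for position.

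Counted against the share of genes per chromosome, X held 74 peaks (21.1%, exact interval 17 to 25.8, against 13.7% of genes; exact binomial adjusted p = 0.000377). Chromosome III held 65 (18.6% against 13.2%; adjusted p = 0.0088, exact binomial) and I held 67 (19.1% against 14.4%; adjusted p = 0.022, exact binomial). Chromosome V, which carries many chemoreceptor genes, held 40 (11.4% against 25%; adjusted p = 1.76e-09, exact binomial). Chromosomes II (60 peaks) and IV (44 peaks) were not past the threshold. Against chromosome length, X (17.7% of the length) and I lost the call, with adjusted p = 0.111 and 0.054 (exact binomial), while IV passed with the lower share (12.6% against 17.4%; exact binomial adjusted p = 0.0328). Without replicate 1, I and III lost it (exact binomial adjusted p = 0.12 and 0.0661), and among the 175 highest peaks I held 14.3%, just under its share of genes.

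**Figure D3:**
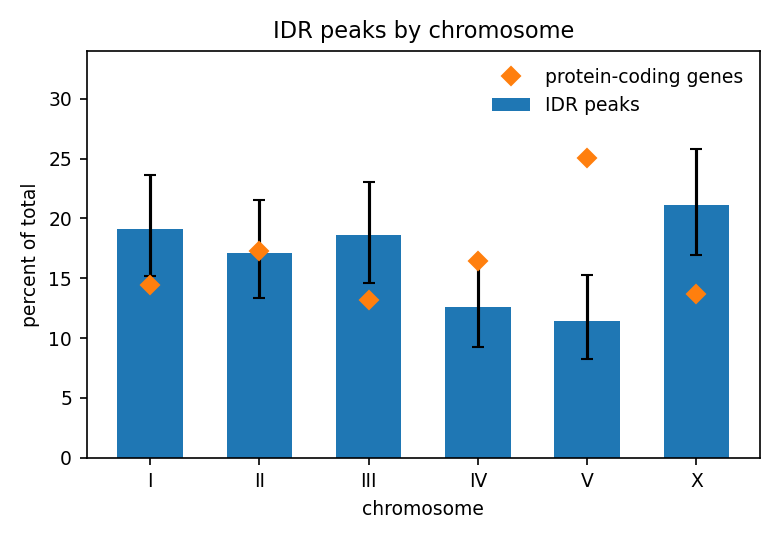
Percent of the 350 IDR peaks on each chromosome (bars, with exact binomial 95% intervals) and percent of protein-coding genes there (diamonds). X, III and I lie above their share of genes, and V lies below.

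Genes of protein synthesis and protein folding stood out among those near peaks. Of 82 ribosomal protein genes, 27 had a start within 1000 bp of a peak summit (32.9% against 1.59% of other genes; Fisher's exact adjusted p = 3.33e-26). They included rpl-3 with a signal of 295, rpl-20 with 200, rpl-35 with 196 and rpl-15 with 136, all for proteins of the large ribosomal subunit. Of 62 heat shock and chaperone genes, 13 were near a peak (21% against 1.66%; Fisher's exact adjusted p = 5.09e-10). Among these were hsp-60, the mitochondrial chaperonin (109), cct-1 and cct-8, subunits of the cytosolic chaperonin (98.7 and 93.9), and hsp-1, a constitutive Hsp70 (88.4).

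Smaller shares were found for translation factors, with 5 of 72 genes (6.94% against 1.70%; Fisher's exact adjusted p = 0.0384), and mitochondrial respiration, with 7 of 123 (5.69% against 1.69%; Fisher's exact adjusted p = 0.0312). The translation factors were led by eif-3.C (signal 99.8), iff-2 for eIF5A (86.2), and the elongation factor genes eef-1A.1 (57.7) and eef-2 (53.5). On the respiration list the highest was cox-5A of complex IV, at peak rank 32. It was followed in signal by atp-1 of the ATP synthase (82.7), nduf-11 of complex I (63.3) and mrpl-28 (60.9), which encodes a protein of the mitochondrial ribosome.

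Chemosensory receptor genes were near peaks less often than other genes, with 2 of 1310 (0.153% against 1.83%; Fisher's exact adjusted p = 3.25e-07). These were sri-5 (signal 78.1) and srh-16 (63.4). The odds ratio of 0.082 stood at 0.185 without replicate 1, 0.162 among the 175 highest peaks, 0.151 at 2000 bp and 0.125 with the closest start only, past the threshold in each. None of 364 innate immunity genes was near a peak, against 1.75% of other genes (Fisher's exact adjusted p = 0.0246; upper exact 95% limit 1.01%). When the background was narrowed to genes with a start near regions of both replicates, respiration, translation factors and immunity lost the call (Fisher's exact adjusted p = 0.189, 0.163 and 0.163) but kept their directions, at 12.5% against 5.85%, 16.1% against 5.86% and 0% against 5.99%. With the closest start only, translation factors and immunity also lost it (Fisher's exact adjusted p = 0.204 and 0.116), as did immunity at 500 bp (adjusted p = 0.0627, Fisher's exact). Among the 175 highest peaks respiration, translation factors and immunity lost it too (Fisher's exact adjusted p = 0.174, 0.554 and 0.396). The odds ratios there were 3.82 for respiration and 3.22 for translation factors, in place of 3.50 and 4.32, and that of immunity stayed at 0. Respiration was higher without replicate 1, with an odds ratio of 7.14 in place of 3.50 (Fisher's exact adjusted p = 4.41e-06), and at 5.36 with the closest start only. In the narrower background ribosomal proteins were near a peak in 37.1% against 5.54%, chaperones in 36.1% against 5.73%, and chemosensory receptors in 0.743% against 6.17%, all past the threshold. The odds ratio of ribosomal proteins was 10.1 there and 20.7 with the closest start only, in place of 30.4. That of chaperones was 9.30 there and 9.50 with the closest start only, in place of 15.7.

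The other 23 of the 29 lists were not past the threshold. Histones, with 5 of 82 genes (Fisher's exact adjusted p = 0.0559), included hsr-9, which is not a histone gene and shared its peak with rps-19. The histone genes his-67 and his-68 shared a peak with each other, and Fisher's test counts such genes as independent. These genes were chosen after their values were seen. The histone list passed with the narrower background (Fisher's exact adjusted p = 0.00443), and also at 500 bp, at 2000 bp, on autosomes and without replicate 2 (0.0258, 0.0147, 0.0408 and 0.0479). It did not pass without replicate 1, where the odds ratio was 2.44 in place of 3.76 (Fisher's exact adjusted p = 0.386), with the closest start only or among the 175 highest peaks (0.245 and 0.211). The proteasome and ubiquitin list had 5 of 85 (Fisher's exact adjusted p = 0.0564) and passed at 500 bp, at 2000 bp, on autosomes and without replicate 2 (Fisher's exact adjusted p = 0.0258, 0.0048, 0.0413 and 0.0484). It did not pass without replicate 1, with the closest start only, with the narrower background or among the 175 highest peaks (Fisher's exact adjusted p = 0.137, 0.0946, 0.213 and 1). Of its 5 genes, ubq-2 was also on the ribosomal protein list and rpn-3 shared its peak with hsp-110, both chosen after their values were seen. Splicing had 3 of 63. Its odds ratio was 5.58 without replicate 1 (Fisher's exact adjusted p = 0.0166) and 0.96 without replicate 2 (Fisher's exact adjusted p = 1). The germline list had 4 of 134, neuropeptides 2 of 146, pharynx 2 of 116, and F-box and MATH/BTB genes 2 of 412. A single gene was found for nuclear hormone receptors (1 of 274), collagens and cuticle (1 of 224), neuronal synapse genes (1 of 148), homeobox factors (1 of 94), bHLH and bZIP factors (1 of 56) and Wnt, Notch and heterochronic genes (1 of 45). No gene was near a peak among 131 of fatty acid metabolism, 90 of hypodermis and seam, 78 vitellogenins and intestine markers, and 51 of muscle. The same held for 75 cytochrome P450, 67 UDP-glucuronosyl transferase, 49 glutathione S-transferase, 40 insulin and TGF-beta, 22 T-box and 12 GATA factor genes. Their upper exact 95% limits ran from 2.78% for fatty acid metabolism to 26.5% for GATA factors, so small lists could not show a lower share.

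**Figure D4:**
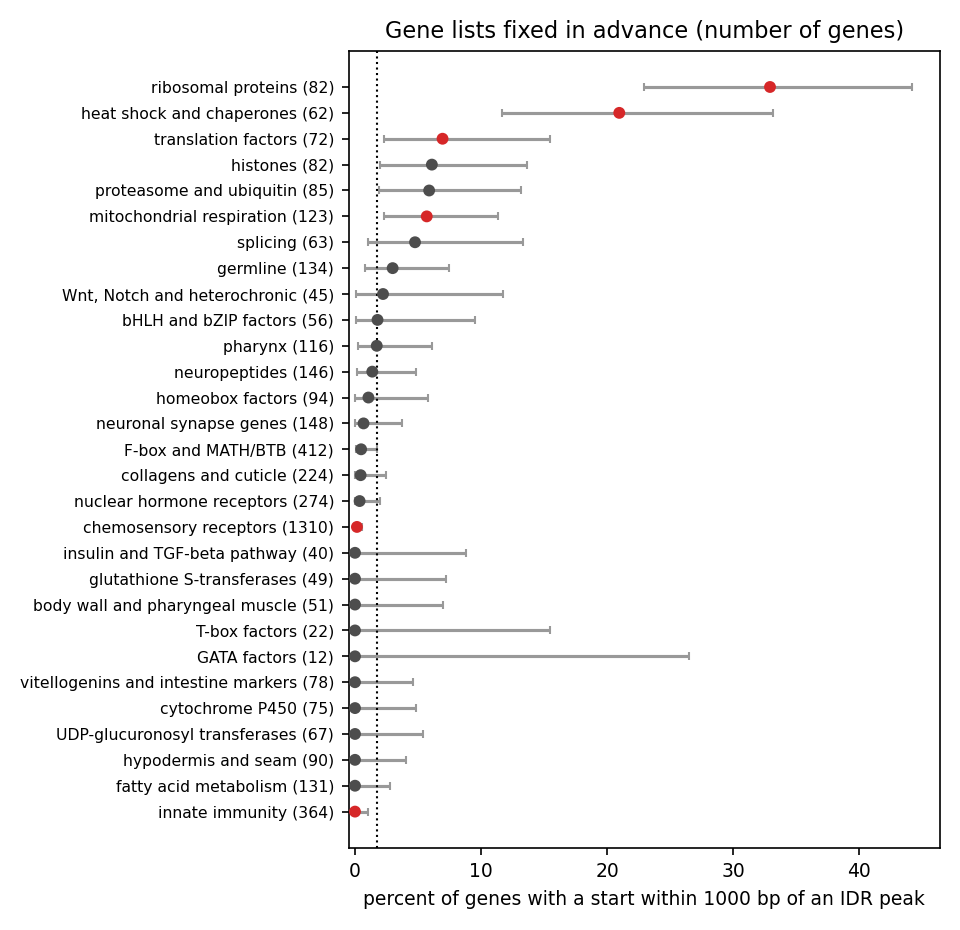
Percent of each list's genes with a start within 1000 bp of an IDR peak (x), with exact binomial 95% intervals and the number of genes in brackets. Red points passed an adjusted p of 0.05, and the dotted line is the 1.72% of all genes.

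Outside the lists that passed, the genes with the closest start at the 25 strongest peaks were nspc-17 on X (signal 316), ZK1248.17 on II (215), Y17G9B.5 on IV (200, in a promoter shared with rpl-20), tasp-1 on III (198), ins-39 on X for an insulin-like peptide (176, one of the 2 on the neuropeptide list), cdc-48.1 on II for the AAA ATPase p97 (174) and drr-2 on III (152). Their summits lay between −736 and 688 bp from the start. Of the 25 named genes with a peak, 24 were also near one of the 350 highest regions of replicate 1 and 22 near one of replicate 2. In replicate 2 the peaks of cct-8, eef-2 and nduf-11 ranked 489, 413 and 2767, and in replicate 1 that of eef-1A.1 ranked 430.

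Small noncoding RNA genes were also marked. Summits within 250 bp of a gene numbered 15 for snoRNA (4.29% of peaks against 0.224% after shuffling), 14 for snRNA (4.0% against 0.0655%) and 12 for tRNA (3.43% against 0.347%), each with an adjusted permutation p of 0.000333, which follows from the smallest possible p of 0.0002. Of the 12 tRNA peaks, 10 were on X, but the share of tRNA genes on X was not determined, so this count has no baseline. A protein-coding start lay within 1000 bp for 3 of the 12 tRNA peaks, 9 of the 14 snRNA peaks and 5 of the 15 snoRNA peaks. Some were also counted for the gene lists, among them the peaks of rps-12, rps-26, hsp-12.3 and cox-6A, chosen after their values were seen. The snRNA class as annotated included 5 sls-2 genes, which encode the SL2 spliced leader that is joined to downstream genes of operons. The strongest of these was sls-2.1, at II 5844865 to 5844974, under the peak named above for ZK1248.17 (signal 215), followed by sls-2.4 (140) and sls-2.2 (111). The sls-2 genes were chosen after their values were seen. In 7 places on the genome 2 IDR peaks overlapped, among them sls-2.1, and with summits within 500 bp merged the snRNA class had 10 of 343 peaks. Without replicate 1 the snoRNA class had 8 peaks (2.29%), and among the 175 highest peaks the tRNA class had 4 (2.29%), both past the threshold. For miRNA genes (2 peaks; adjusted permutation p = 0.223) and rRNA genes (0 peaks) the threshold was not passed.

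The sequence around the 233 summits near starts differed from that at the same distance from random starts. The GA repeat GAGAGAG was present in 14.6% of windows against 4.03% (Fisher's exact adjusted p = 2.6e-08) and CCGCCC, a KLF/SP type motif, in 11.2% against 4.85% (Fisher's exact adjusted p = 0.000613). A C/EBP type motif was also more frequent (20.6% against 8.93%; Fisher's exact adjusted p = 9.85e-07). The GATA factor motif TGATAA, typical of intestinal promoters, was less frequent (7.30% against 20.9%; Fisher's exact adjusted p = 3.18e-07), as was AGTTCA (6.44% against 14.5%; Fisher's exact adjusted p = 0.000676). For TGATAA the odds ratio of 0.297 stood at 0.520 without replicate 1 (11.6% against 20.2%) and 0.177 within 50 bp, past the threshold in both. The nuclear receptor hexamer AGGTCA was found in 5.15% against 5.54% (Fisher's exact p = 1), with an odds ratio of 0.926 (1.07 without replicate 1). None of the DAF-12 type AGTGCA, HNF4 type, AP-1 type, E-box and heat shock motifs passed the threshold. Within 50 bp of the summit the heat shock motif did, with the lower share (2.58% against 6.95%; Fisher's exact adjusted p = 0.0213), at an odds ratio of 0.354 in place of 0.729, but without replicate 1 it was 1.03. With dinucleotide-shuffled copies of the same windows as controls, only the GA repeat and CCGCCC passed, and the C/EBP type motif stood at 20.6% against 19.4% and TGATAA at 7.30% against 8.84%. There AGTTCA kept its direction without passing (6.44% against 11.6%; Fisher's exact adjusted p = 0.058), and it also missed the threshold without replicate 1 (Fisher's exact adjusted p = 0.0533).

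No IDR peak lay within 20000 bp of nhr-237 (V 1625189 to 1626820), the tagged gene, or of unc-119 (III 10902641 to 10908935), whose mutation marks the strain. Shuffling gave means of 0.0814 and 0.226 peaks, so a count of 0 was the usual outcome (one-sided permutation p = 1 for both).

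Peaks near starts did not differ in signal from the others over the whole list, with medians of 59.3 (233 peaks) and 55.4 (117 peaks; two-sided permutation p = 0.313). In the 350 highest regions of replicate 2 alone those near starts had the higher median by 1.61 (permutation p = 0.0486), and among X peaks the lower one by −9.57 (27 against 47 peaks; permutation p = 0.565).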

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

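The splits into X and autosomal peaks, the 25 and 100 highest regions, and the merging of summits for noncoding classes and chromosomes were chosen after seeing the data; the other alternatives were fixed before. The share of peaks near starts stayed between 56.3% and 76.6% and past its threshold under the 6 settings fixed before and on autosomes, but not for X peaks alone, at 36.5%. Replicate overlap stayed past its threshold in all 8 alternatives, between 29.5% and 88%. The 3 noncoding classes passed in every alternative run, with the snoRNA class at 2.29% without replicate 1, and the count of peaks at nhr-237 and unc-119 stayed at 0. The number of gene lists past the threshold was 6 and fell to 3 with the 175 highest peaks, where fewer peaks were tested, leaving ribosomal proteins, chaperones and chemosensory receptors. These 3 lists passed in every alternative. With one replicate alone 7 or 8 lists passed. The number of chromosomes past the threshold was 4, and ranged from 2 to 4 with one replicate left out; without replicate 1 chromosomes I and III lost the call. Chromosome I fell from 19.1% to 14.3% among the 175 highest peaks, below its share of genes, and the cause was not tested. Motifs past the threshold fell from 5 to 2 with dinucleotide-shuffled controls, which keep the base composition of the peaks. The signal difference of 3.83 by location turned to −16.2 among the 175 highest peaks, which were chosen by the signal compared, so this is no test of location. It was −9.57 for X peaks alone, not past the threshold. Without replicate 2 it was 0.829 and without replicate 1 it was 1.61. Both are on the scale of the replicate list used, so their sizes cannot be set against 3.83. Of these, only the difference without replicate 1 was past the threshold, and the cause was not tested. Among single lists, classes, chromosomes and motifs, 317 of the alternatives left the call as it was, 17 ended a call in the same direction, 12 added one, and 1, chromosome I as given above, ended a call and turned its direction. Without read counts or an untagged control, depth and background precipitation could not be varied.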

Other observations

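The tests of an X-wide rise, of promoters listed in general and of both explanations for the gap at nhr-237, and the searches over name families and 6-base words, were chosen after the result was seen.

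Grouping all genes by the prefix of their name gave 419 families of at least 5 genes, and 6 of them passed an adjusted p of 0.05, all with more genes near a peak. Ribosomal (rpl, rps) and chaperone (hsp, dnj) prefixes were already covered by the lists. A further one was sec, with 6 of 19 genes (31.6% against 1.69%; Fisher's exact adjusted p = 7.7e-05). Its members were sec-61.A, sec-61.B and sec-61.G of the translocon through which proteins enter the endoplasmic reticulum (signals 46.4, 44.1 and 105), sec-24.1 of the COPII coat (68.3), and sec-3 and sec-15 of the exocyst (45.7 and 44.3). The sec-61.A start shares its peak with rps-18. The other was lin, a prefix for lineage phenotypes and not for a pathway, with 7 of 47 genes (14.9%; Fisher's exact adjusted p = 0.00121). Of these, lin-9 (63.3), lin-53 (58.3) and lin-54 (116) encode subunits of the DREAM complex, and the lin-54 start shares its peak with rpl-12. They were picked out after their values were seen, and the genes of that complex were not tested as a set. The others were lin-23, lin-36, lin-59 and lin-66.

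Among all 2080 words of 6 bases, 220 were more frequent around the 122 start-proximal summits of odd rank than in offset-matched windows, and 153 of those passed again in the 111 of even rank. The leading word, GACGCA, was present in 33.6% of odd-rank windows against 4.26% and in 29.7% of even-rank windows against 5.14% (Fisher's exact adjusted p = 5.87e-18 and 1.33e-12). AGCGCG was in 23% against 2.62% and 25.2% against 2.61%. These words are rich in CG, and the base composition of the peaks was not matched in that search.

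The 15 strong X peaks away from starts may be recruitment sites of the dosage compensation complex, which binds X in hermaphrodites. The core of its X motif, TCGCGCAGGG with at most 1 mismatch, lay within 100 bp of 11 of the 15 summits (73.33%), compared with 0.18% of 5000 random X windows away from starts and 0.667% of dinucleotide-shuffled copies (Fisher's exact adjusted p = 1.82e-24). Over all X peaks away from starts it was in 14 of 47 (29.8%; Fisher's exact adjusted p = 1.69e-23), so most of them lack it. The 47 include the 15 strong peaks, which hold 11 of those 14, so this test largely repeats the one before. X peaks near starts had the core in 2 of 27 (7.41%; Fisher's exact adjusted p = 0.00494). Sequence repeated in the assembly is argued against by a median of 100% of 36-base words that occur once. A rise along all of X could not be decided, because the answer depends on the measure. X held 17.8% of the weaker pooled regions, close to its 17.7% of the length (ratio 1.01) but above its 13.7% of the genes. AGGTCA was in 0 of the 15 (0%) against 5.68% of random windows (exact p = 1), too few to decide on binding of the receptor at that hexamer, whose own site is not known here. The share was highest in autosomal peaks away from starts, with 7 of 70 (10% against 4.48%; Fisher's exact adjusted p = 0.0974), and was not past the threshold in any set. Dinucleotide-shuffled copies of those 70 windows held the hexamer in 7.57%, so base composition goes with much of that difference. Whether NHR-237 is present at these sites or they are recovered whatever protein is precipitated stays open, because no untagged precipitate was analysed here.

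The 41 peaks at ribosomal protein and chaperone promoters may reflect how strongly these promoters are transcribed, for which no measurement was used here. Being listed at the relaxed threshold accounts for part of it at most, since the odds ratio of ribosomal proteins fell from 30.4 to 10.08 among genes near regions of both replicates and stayed past the threshold (Fisher's exact adjusted p = 1.41e-13). Reads shared between copies are argued against by a median of 100% of 36-base words that occur once. AGGTCA was in 0% of these peaks against 5.71% of windows at the same offsets (exact p = 0.167; upper limit of the odds ratio 1.58), so binding of the receptor at that hexamer cannot be told apart from its absence. Open chromatin and background precipitation at active promoters were not tested.

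Around nhr-237 neither replicate had a region summit from V 1607711 to 1643726, a stretch of 36016 bp with 12 protein-coding genes. The regions at its edges may reach into it. The median stretch around a gene without summits in both replicates was 2882 bp over all chromosomes. Taken in each replicate alone, the gap between summits at nhr-237 was 40806 bp in replicate 1 and 36813 bp in replicate 2. The median of such gaps in the first 5 Mb of V was 5608 bp and 5645 bp. Over all chromosomes, 5 stretches were at least as long with this one counted, 4 of them on V, and together they held 0.441% of genes. A region poor in sites stays open: in the first 5 Mb of V, 48 of the 1141 genes outside this gap (4.207%, exact 95% interval 3.12 to 5.54) lay in a gap as long in both replicates. The interval spans the bound of 5% set for this test, the genes fall in only 2 other gaps, and with the 12 genes of this gap the share was 5.2%. Leaving these genes out and using the interval was decided after that share was seen. Of the words in the stretch, 95.3% occur once. Extra copies of the locus in the control could also empty it, and the replicates share 86.58% of the gap, but both were called against a control whose strain is not given in the sources used here, so these explanations cannot be told apart.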
